A study of Pardosa pseudoannulata with 16 samples.

How the data were processed

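RNA was measured in whole spiders of Pardosa pseudoannulata, a wolf spider that hunts insects in rice fields. Poly-A RNA was purified, fragmented, copied into cDNA with random primers and sequenced on an Illumina instrument, per the labels' protocols. The table holds 16 libraries in 4 groups named Ck, UL, UM and UH, with 4 libraries per group. Groups and replicate numbers were taken from the labels. Nothing in the labels says that replicates came from separate animals or pools, so p-values measure the spread between these samples, which may be technical.

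The design text gives 3 urea concentrations in soil (0, 200 and 400 mg/kg) and an exposure of 30 days. It does not tie 3 concentrations to 4 groups, and the labels give every sample, Ck included, the same treatment. No concentration was therefore assigned to any group, and no order of the groups was used. Ck was taken as the reference because the name is a usual abbreviation of a control; the labels do not spell it out.

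The deposited table lists FPKM (fragments per kilobase of sequence, scaled to the mapped fragments of the library), calculated by the authors and rounded to 2 decimals, per the file headers and the values. Its rows are 136360 sequence clusters with names of the form Cluster-number.number, each with the length listed by the authors, which was taken to be in bases (301 to 45289, median 599). The first number of the name is the same for 102255 clusters (75.0%), among them every cluster named in the text. The assembler, the aligner and the counting tool are not given in the sources used here. The submitters' processing notes name the build mm10, which is a mouse genome and does not match the organism; the clusters carry no chromosome positions. The table pairs no cluster with a gene name or description, and no reference was used here. Lists of genes by function, written before the data were examined, could for that reason not be matched to clusters, and the planned camera and fry tests of those lists were not run. One transcript can be split over several clusters and related sequences can share fragments, so a cluster is not equated with a gene.

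FPKM carries no total per library, so depth was estimated from the low values. In clusters of one length, values in a library fall on whole multiples of the FPKM of 1 fragment. A grid search over depth and mean fragment length, the latter entering through an effective length with a normal spread, found the step that made low values most nearly whole. It gave 16.57 to 20.76 M (mega) fragments per library, a ratio of 1.25 between the deepest and the shallowest, with mean fragment lengths of 256 to 292 bases. Of the values worth 1 to 10 fragments in clusters of up to 900 bases, 98.6 to 98.9% came out whole within 0.1 of a fragment. Summed over all clusters, the estimated fragments came to between 100.1 and 100.3% of the estimated depth. The depth cancels in this share, and the search for the fragment length started from it, so it does not test the depth. On simulated libraries of 136360 clusters the largest depth error was 0.900%. These were drawn with the same model of effective length that the search fits. Their error therefore does not test whether that model holds for the deposited values. At these depths 1 fragment on a cluster of 500 bases is worth 0.207 to 0.257 FPKM, and less on a longer cluster. It is worth more on a shorter cluster, most of all near the mean fragment length. Because these fragments are estimates, no count model was used as the main test.

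Clusters with at least 1 FPKM in at least 4 libraries were tested (36003). Values entered as log2(FPKM + 1), with a pseudocount of 1, so a log2 fold change understates the change of clusters with low values. All 16 libraries were fitted together in limma 3.58.1 (R 4.3.3) with a mean-variance trend, which leaves 12 residual degrees of freedom. The 6 pairwise comparisons were two-sided, each with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A limma F test over the 3 contrasts against Ck asked for any difference among the 4 groups. On data simulated for the UH and Ck comparison from these 36003 clusters, with 200 changed, 49% of changes of log2 size 1 were recovered with 7.55% of the calls false. For log2 size 2 the figures were 82% and 2.38%. The simulation drew independent normal values with the same spread in all groups, and changed only clusters with a mean log2 value over 1. Real clusters move together and the Ck libraries spread wider than the other groups. These figures therefore do not give the recovery or the false share in the real data. All adjusted p-values of clusters in the text are from limma unless another test is named.

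Principal components and variance shares used the same log2 values. Single values per library were compared by two-sided exact permutation tests, whose smallest possible p with 4 against 4 libraries is 0.0286. The share of variance between groups was tested one-sided, with 100000 permutations for the 4 groups and with all 35 splits for each pair. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. No pair of libraries was a duplicate; the highest correlation between 2 libraries was 0.936.

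The rule for naming clusters was fixed before the data were examined. With no descriptions it names at most 2 clusters that rose and 2 that fell in each comparison against Ck, those with the largest change among calls whose 4 and 4 values do not overlap. Alternatives fixed at the same time were a pseudocount of 0.1, no filter on low values, rescaling by the median ratio to the geometric mean, quantile normalization, the replicate number as a block, a fit of only the 2 groups compared, limma array weights, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Leaving out a library kept the other 15 in one fit. Alternatives chosen after seeing the data were limma voom on the estimated fragments, clusters of at least 500 bases only, no clusters listed at 0 in a whole group, and 4 libraries left out together (Ck replicates 1 and 2, UL replicate 3, UM replicate 3). For comparisons sharing the Ck libraries, 100 sets of unchanged groups were simulated. In each, the deviations of all 16 libraries from their group means were shuffled over the libraries, with random signs. The simulated Ck libraries thus carry deviations from all groups and not those of the real Ck libraries. The behavioural, enzyme, microbiota and metabolite measurements named in the design text were not analysed here.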

Results

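The study asked how urea, a nitrogen fertiliser, affects the wolf spider Pardosa pseudoannulata. The RNA part of it, analysed here, compared whole spiders in 4 groups named Ck, UL, UM and UH, with n = 4 libraries each. Estimated depth in replicates 1 to 4 was 19.63, 20.76, 17.57 and 18.83 M (mega) fragments in Ck. It was 18.84, 19.22, 19.35 and 18.65 M in UL. The UM libraries held 18.5, 18.82, 16.57 and 18.82 M, and the UH libraries 18.37, 19.37, 19.38 and 19.26 M. Between 76712 and 97015 of the 136360 sequence clusters were listed above 0 in a library, and 369 were listed at 0 in every library.

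A single cluster, Cluster-9253.47764 (703 bases), was the most abundant in all 16 libraries and took 6.22 to 15.9% of a library's FPKM sum. Its mean was 52395 FPKM ± 4508 in Ck, 72870 ± 43460 in UL, 105631 ± 19594 in UM and 73024 ± 14909 in UH (SD, n = 4). All UM and all UH values lay above all Ck values, with ratios of means of 2.02 and 1.39. Each of these 2 differences had p = 0.0286 in an exact permutation test, the smallest such a test can give. Neither passed adjustment over the 30 tests of library measures (0.143).

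The 4 groups differed in their overall profile. Group means took up 43.4% of the variance of the tested clusters (p = 1e-05, the smallest that 100000 permutations can give). Random groups of the same size also take up part of the variance. This share, like those between pairs of groups below, is therefore not the size of a group effect. On the first principal component (30.5% of variance) the UH libraries lay between -86.5 and -68.6 and the UL libraries between 64.9 and 117.2. The Ck libraries spread between -43.9 and 105.6, wider than any other group. Correlations between Ck libraries ran from 0.754 to 0.908, against 0.879 to 0.933 between UH libraries; these are correlations across clusters, which are not independent replicates. The limma F test called 6789 of 36003 clusters as differing among the groups, and 13082 had an unadjusted p under 0.05. That count was 3604 without UH replicate 1 and 3886 without UH replicate 2.

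**Figure D1:**
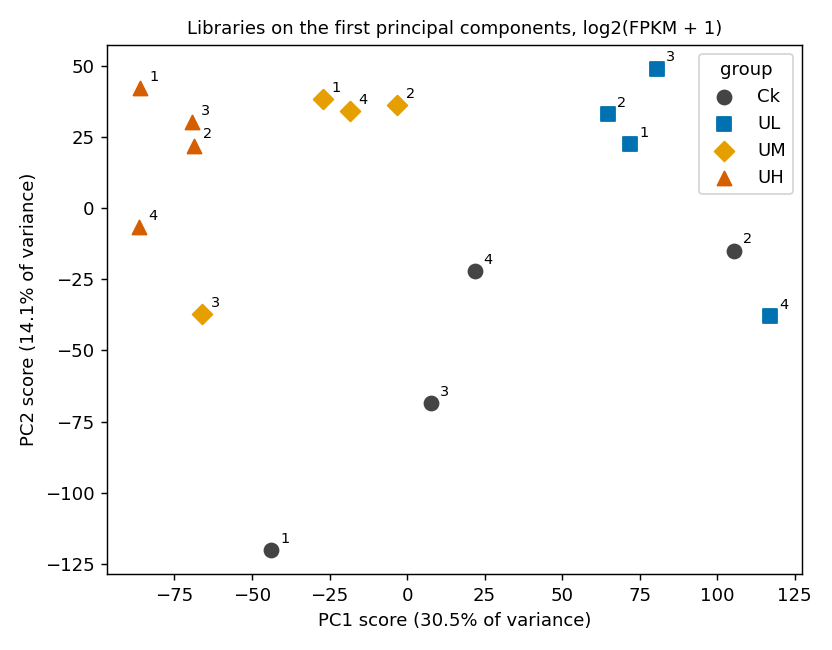
Each point is 1 of the 16 libraries, placed by its scores on the first (x axis, 30.5% of variance) and second (y axis, 14.1%) principal components of log2(FPKM + 1); scores have no unit, colour and shape give the group, and the number beside a point is its replicate. UH libraries lie at the left (-86.5 to -68.6), UL libraries at the right (64.9 to 117.2), and Ck libraries range from -43.9 to 105.6 on the x axis.

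UL against Ck asks how the group UL differs from the reference. In the main fit few clusters separated them. Cluster-9253.50222, the longest of the named clusters at 11556 bases, had 9.54, 33.32, 12.59 and 13.37 FPKM in the Ck libraries and was listed at 0 in all 4 UL libraries (adjusted p = 7.13e-06); it was also listed at 0 in the UM and UH libraries. Cluster-9253.22097 (317 bases) had 3.92, 7.16, 2.0 and 2.47 FPKM in Ck and was listed at 0 in UL (adjusted p = 0.0158). On so short a cluster these Ck values amount to few fragments. In the other direction, Cluster-9253.40419 (302 bases) was listed at 0 in all Ck, UM and UH libraries and had 2.94, 3.14, 1.06 and 3.64 FPKM in UL (adjusted p = 0.00813). These UL values likewise amount to few fragments, so the call rests on values near the floor.

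In all, limma called 6 of 36003 clusters between UL and Ck, of which 1 rose and 5 fell, and 6037 had an unadjusted p under 0.05. With array weights it called 1099, of which 225 rose and 874 fell, and with 4 libraries left out together 2250. The profiles of UL and Ck were not separated by a test of the variance between them (23.7%, exact permutation p = 0.114). The count rested on single libraries: it was 2135 without Ck replicate 2, 32 without Ck replicate 3, 30 without Ck replicate 4 and 2 without UL replicate 1, and no cluster passed in a fit of the UL and Ck libraries alone (4059 with an unadjusted p under 0.05). The call on Cluster-9253.22097 was lost without Ck replicate 1 or UL replicates 1, 3 or 4 and that on Cluster-9253.40419 without UL replicate 1 (highest adjusted p with a library left out 0.078 and 0.0726); over other settings the 2 calls were lost in 3 of 9 and 2 of 9, and that on Cluster-9253.50222 in 1 of 10 (highest adjusted p 0.202, 0.202 and 0.0668).

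UM against Ck gave changes in both directions. Cluster-9253.41983 (3832 bases) rose from 3.33, 0.62, 0.16 and 1.62 FPKM in Ck to 17.8 ± 4.06 in UM (SD, n = 4), with a log2 fold change of 3.10 ± 0.32 (SE; adjusted p = 0.00153). Cluster-9253.17447 (325 bases) was listed at 0 in Ck replicates 2, 3 and 4, had 6.75 FPKM in Ck replicate 1, and had 11.16 to 29.97 FPKM in UM (log2 fold change 3.45 ± 0.59, adjusted p = 0.0422). Cluster-9253.48350 (1842 bases) had 311.46, 469.81, 278.89 and 8.63 FPKM in Ck and was listed at 0 in every UM library (adjusted p = 0.0146). Cluster-9253.48374 (844 bases) fell from 361.1 FPKM ± 277.6 to 0.960 ± 0.541, with 11.15 FPKM in its lowest Ck library (log2 fold change -6.60 ± 1.08, adjusted p = 0.0324). It ranked the Ck libraries in the same order as Cluster-9253.48350, so these falls are not taken as independent.

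The comparison of UM with Ck called 36 clusters, 18 that rose and 18 that fell, and 4124 had an unadjusted p under 0.05. The variance between UM and Ck was 27.3% (exact permutation p = 0.0286, adjusted over the 6 pairs 0.0343), and the highest other split reached 23.4%. The count was 341 without Ck replicate 2, 93 without Ck replicate 4, 21 without Ck replicate 3, and 16, 22 and 18 without UM replicates 1, 2 and 3, and it was 5 in a fit of the UM and Ck libraries alone. With single libraries left out, the call on Cluster-9253.17447 was lost without Ck replicates 3 or 4 or any UM library, that on Cluster-9253.48374 without Ck replicates 1 or 3 or any UM library, and that on Cluster-9253.48350 without Ck replicate 3 or UM replicates 1 or 3 (highest adjusted p 0.137, 0.126 and 0.058); over other settings these calls were lost in 7 of 10, 6 of 11 and 3 of 10, and that on Cluster-9253.41983 in 1 of 11 (highest adjusted p 0.208, 0.296, 0.36 and 0.0701).

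UH against Ck gave the most changes of the comparisons with Ck. Cluster-9253.84883 (1498 bases) had 0.04, 0.04, 0 and 0.26 FPKM in Ck and 1654.27, 3198.14, 99.96 and 501.04 FPKM in UH (log2 fold change 9.38 ± 1.25, adjusted p = 0.00109). Cluster-9253.14435 (1837 bases) rose from at most 0.13 FPKM in Ck to 187.01, 351.84, 15.07 and 47.06 FPKM in UH (log2 fold change 6.32 ± 1.12, adjusted p = 0.00532). It ranked the UH libraries in the same order as Cluster-9253.84883, so these rises are not taken as independent. Cluster-9253.46820 (1367 bases) fell from 350.1 FPKM ± 276.8 in Ck to 0.143 ± 0.0685 in UH, with 76.42 FPKM in its lowest Ck library (log2 fold change -7.81 ± 0.78, adjusted p = 0.000113). Cluster-9253.52189 (339 bases) had 59.44, 177, 151.02 and 777.06 FPKM in Ck and was listed at 0 in every UH library (adjusted p = 0.000523).

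Between UH and Ck 4049 clusters passed (11.2% of those tested), of which 1219 rose and 2830 fell. In 3214 of them the 4 UH values and the 4 Ck values did not overlap; 17.1% of all tested clusters had no overlap, where chance gives 2.86%. The median log2 fold change was 1.37 among those that rose and -0.79 among those that fell. In bands of abundance chosen after the values were seen, among clusters with a mean under 10 FPKM 808 rose and 2190 fell, and among those over 100 FPKM 47 rose and 43 fell. Of the calls, 184 were listed at 0 in all UH libraries and 25 in all Ck libraries. Clusters listed above 0 averaged 78050.5 per UH library and 87581 per Ck library (exact permutation p = 0.0286, adjusted over the 30 tests of library measures 0.143). Whether this difference bears on the falls was not tested. The variance between UH and Ck was 35.4% (exact permutation p = 0.0286, adjusted 0.0343).

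The balance of rises and falls in UH depended on scaling. The median log2 fold change of all tested clusters against Ck was -0.15 as deposited and -0.00 after median ratio scaling, under which 2024 clusters rose and 1562 fell; with quantile normalization 1746 rose and 1477 fell. The share that fell was therefore 69.9% as deposited, 43.6% and 45.8%; as deposited it was 55.2% among calls with an absolute log2 fold change of at least 1 (867 rose and 1070 fell). The count was 2395 without Ck replicate 3, 1984 without Ck replicate 4, 1709, 1815 and 2222 without UH replicates 1, 2 and 4, and 1171 in a fit of the UH and Ck libraries alone. The calls on Cluster-9253.84883, Cluster-9253.14435, Cluster-9253.46820 and Cluster-9253.52189 held with any 1 of the 8 UH and Ck libraries left out (highest adjusted p 0.022), and 1 call, that on Cluster-9253.52189, was lost under another setting (adjusted p = 0.0618 with limma voom on estimated fragments; 1.94e-05 to 0.0618 over 9 settings).

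**Figure D2:**
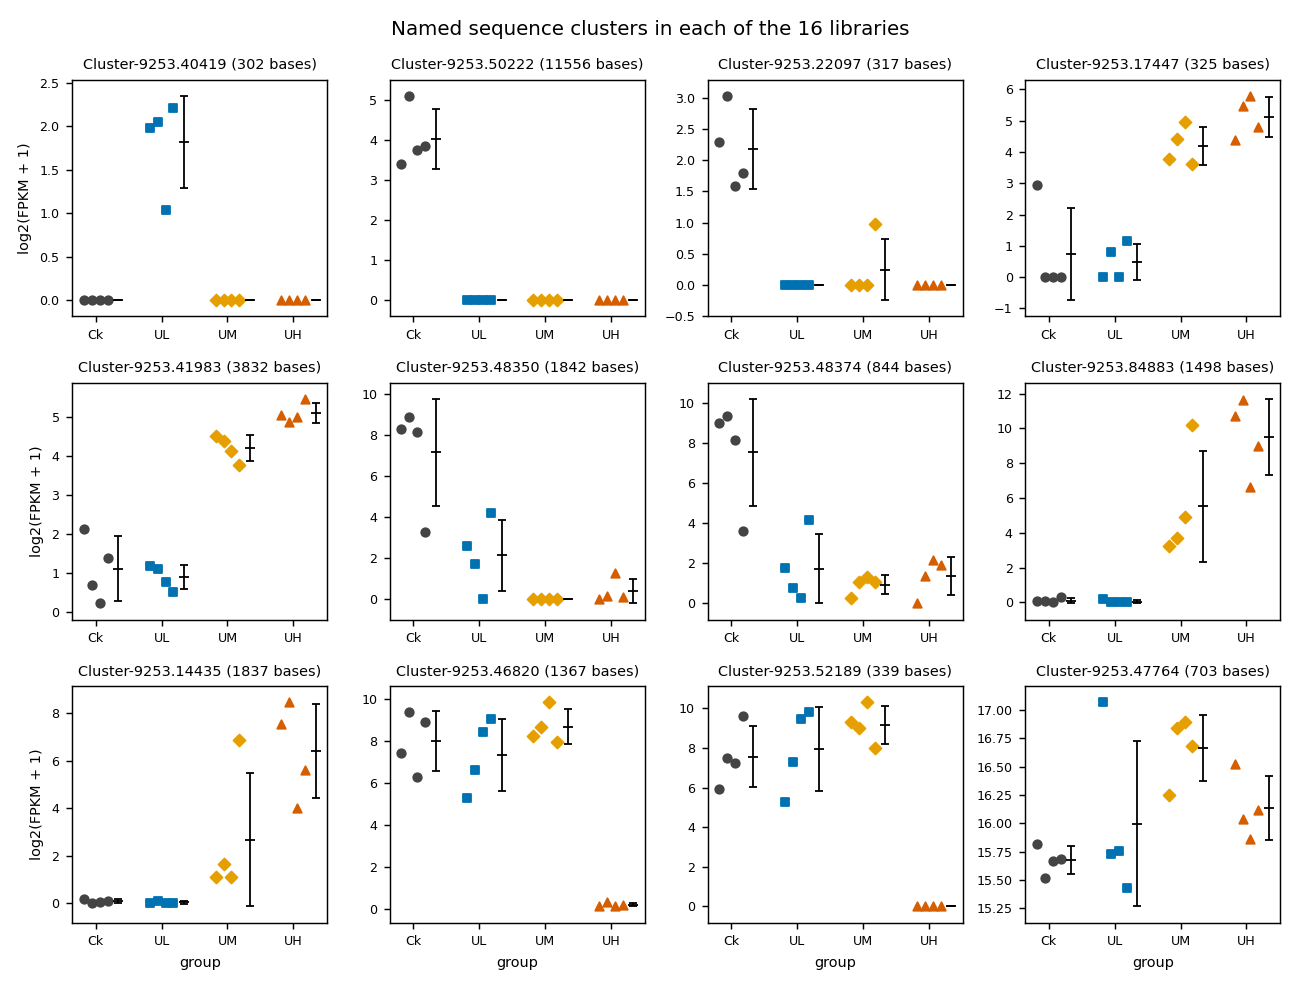
Each panel plots log2(FPKM + 1) of 1 named cluster (y axis, scaled per panel) against group (x axis), with 1 point per library in the order of replicates 1 to 4 and, at the right of each group, the mean with an SD bar (n = 4). Cluster-9253.50222 lies above 0 only in Ck, Cluster-9253.46820 falls to 0.09 to 0.24 FPKM in UH, and Cluster-9253.84883 reaches 99.96 to 3198.14 FPKM in UH.

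The comparisons against Ck share the Ck libraries, so their fold changes are related even with no effect. Simulations of unchanged groups drew the Ck deviations from the libraries of all groups, while the real Ck libraries spread wider. Values outside the simulated ranges are therefore not read as a shared effect or as its absence. Across clusters, UM and UH changes against Ck had r = 0.66, inside the central 95% of simulations of unchanged groups (0.12 to 0.79, median 0.50), and r between 0.18 and 0.48 when the Ck libraries were split. Their covariance was 0.290, above the simulated 0.0138 to 0.164 (median 0.0747), a difference of 0.215 from the median. For UL and UM r was 0.30, inside the simulated 0.00 to 0.74 (median 0.53), as was the covariance of 0.108 (median 0.0743); split r ran from -0.22 to 0.39. For UL and UH r was 0.13, below the simulated 0.22 to 0.78 (median 0.54), with a covariance of 0.0561 inside the simulated 0.0278 to 0.163 (median 0.0803) and split r from -0.31 to 0.20. UM and UH shared 8 clusters that rose and 18 that fell, beside 0.609 and 1.41 for independent lists, which leave out the shared Ck libraries, and 0 in the simulations, which leave out the effects. Neither gives the overlap expected without a shared effect. Cluster-9253.50222 was among the 4 clusters that fell in all 3 groups against Ck (adjusted p = 2.69e-06 in UH), and 0 rose in all 3.

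UM against UL compares 2 of the groups whose names start with U, without any order of concentration. Cluster-9253.41983 and Cluster-9253.17447 were again higher in UM (log2 fold changes 3.32 ± 0.32 and 3.70 ± 0.59, adjusted p = 0.000969 and 0.0224); in UL the second had 0, 0.75, 0 and 1.21 FPKM. Cluster-9253.84883 had 8.62, 11.91, 29.48 and 1159.7 FPKM in UM and at most 0.13 FPKM in UL (log2 fold change 5.47 ± 1.25, adjusted p = 0.0339). Cluster-9253.40419 was listed at 0 in UM (adjusted p = 0.00406), and its values in UL amount to few fragments. The call on Cluster-9253.84883 was lost without any 1 UL library or UM replicates 1 or 3 and in 4 of 11 other settings (highest adjusted p 0.106 and 0.216), and that on Cluster-9253.17447 without UL replicate 3 or UM replicates 1 or 3 (highest 0.0683). In total 1159 clusters passed, of which 945 rose and 214 fell, and the variance between the groups was 36.1% (exact permutation p = 0.0286, adjusted 0.0343).

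The share that fell was 18.5%, and 17.1% after median ratio scaling; with quantile normalization it was 31.9% (1000 rose and 469 fell). The count was 137, 87, 16 and 37 without UL replicates 1, 2, 3 and 4, and 20, 369 and 28 without UM replicates 1, 2 and 3; it was 839 without UM replicate 4, was 67 with no filter on low values, and came to 2044 with array weights.

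UH against UL gave the most calls of the 6 comparisons. Cluster-9253.46820 was lower in UH (0.09 to 0.24 FPKM) than in UL (38.04, 97.45, 342.44 and 526.33 FPKM; log2 fold change -7.15 ± 0.78, adjusted p = 9.29e-05). Cluster-9253.41983 was higher in UH, 33.9 FPKM ± 6.52 against 0.878 ± 0.391 (log2 fold change 4.22 ± 0.32, adjusted p = 9.44e-06). Cluster-9253.17447 was higher too, 19.9 to 54.26 FPKM against at most 1.21 (log2 fold change 4.62 ± 0.59, adjusted p = 0.000281). Of 36003 clusters 10348 passed, 3195 that rose and 7153 that fell, and 8558 of them had no overlap between the 4 and 4 values. The variance between UH and UL was 46.2% (exact permutation p = 0.0286, adjusted 0.0343).

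The median log2 fold change of all tested clusters between UH and UL was -0.27, and -0.04 after median ratio scaling, which gave 4558 that rose and 2368 that fell. Quantile normalization gave 3800 and 4030, so the share that fell was 69.1% as deposited, 34.2% and 51.5%. As deposited, the majority also turned among calls with an absolute log2 fold change of at least 1, where 2387 rose and 1323 fell (35.7%). With any 1 of the 8 libraries left out, between 7585 and 11498 clusters passed.

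UH against UM separated the groups mainly through clusters that were lower in UH. Cluster-9253.46820 had 249.94 to 930.62 FPKM in UM and 0.09 to 0.24 FPKM in UH (log2 fold change -8.50 ± 0.78, adjusted p = 0.000161). Cluster-9253.52189 had 250.26 to 1267.63 FPKM in UM and was listed at 0 in UH (adjusted p = 0.000231, but 0.0619 with limma voom on estimated fragments). For Cluster-9253.41983 and Cluster-9253.17447 the difference between UH and UM did not pass (log2 fold changes 0.90 ± 0.32 and 0.92 ± 0.59, adjusted p = 0.14 and 0.399). In total 1017 clusters passed, of which 100 rose and 917 fell, and the variance between the groups was 31.0% (exact permutation p = 0.0286, adjusted 0.0343).

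The median log2 fold change between UH and UM was -0.19, and 0.01 after median ratio scaling, with 197 that rose and 330 that fell; quantile normalization gave 147 and 353. The share that fell was 90.2% as deposited, 62.6% and 70.6%. The count was 377, 484 and 518 without UH replicates 1, 2 and 3, 610, 401, 553 and 599 without UM replicates 1, 2, 3 and 4, and 4825 with array weights.

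**Figure D3:**
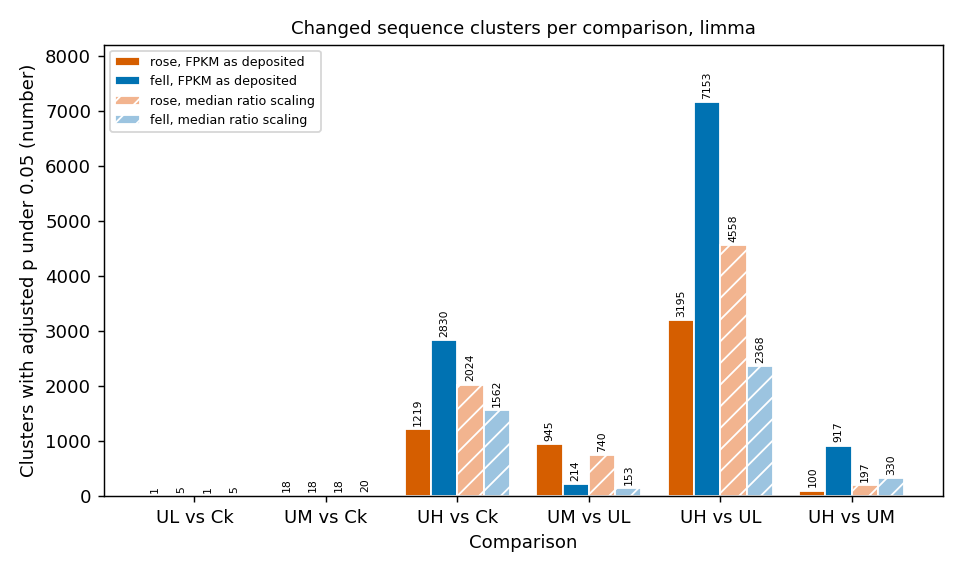
Bars give the number of clusters with a limma adjusted p under 0.05 (y axis) in each of the 6 comparisons (x axis), split into those that rose and those that fell in the first-named group, with FPKM as deposited (solid) and after median ratio scaling (hatched); bars carry no error. UH against UL has 3195 and 7153 as deposited and 4558 and 2368 after rescaling, so the direction of the majority turns there and in UH against Ck.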

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

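The tests without the 10 most abundant clusters, of depth by voom, of the scaling in FPKM, of the depth of UL replicate 3 and of its clusters with 10 or more and with under 10 estimated fragments were chosen after the results were seen. The other tests in this part were set before their own results were seen, though after the patterns they test had been noticed. An earlier form of the test without the 10 most abundant clusters also set all libraries to one FPKM sum and gave a median log2 change of -0.21, but equal sums alone moved it from -0.15 to -0.20. The form used here was first held to a bound of -0.1, which 1 of its 3 ways missed narrowly with libraries left out, and then to -0.05, the edge of what the explanation needs; both bounds were set with values of the test already seen.

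Chance was tested by regrouping the libraries. Between UH and Ck, 1 of the 35 splits of the 8 libraries, the real one, gave as many calls (4049; highest other 7). The real split was also the 1 split of 35 with as many calls between UM and UL (1159; highest other 5), UH and UL (10348; highest other 17) and UH and UM (1017; highest other 10). Among the 4 groups, 1 of 100 groupings, the real one, gave as many (6789; highest other 1559). A random regrouping of these libraries is thereby argued against for these 5 counts, at a share under 0.05. The smallest share that 35 splits can give is 0.0286, and the shares were not adjusted over the pairs. The UM to UL count fell as low as 16 with 1 library left out. If replicates are technical, regrouping them does not address chance differences between animals. Chance is not excluded for UL against Ck, where 7 of 35 splits gave at least 6 calls and the highest other gave 284. Nor is it for UM against Ck, where 2 of 35 gave at least 36. In that pair the split of Ck replicates 1, 3 and 4 with UM replicate 3 against the rest gave 614 calls, many times the real count. The next highest other split gave 7, and what sets the split with 614 apart was not tested.

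More clusters fell than rose in UH against Ck (2830 and 1219), and 3 technical explanations were tested. A lower depth of UH is argued against, since depths overlapped. In limma voom on estimated fragments 71.9% of the calls still fell. That fit scales each library by its own depth, as FPKM does, so its share adds little. Scaling down by the 10 most abundant clusters is argued against as the whole cause. Without them, each library kept at its own sum, the median log2 change was -0.15 (-0.16 to -0.14 in 3 ways). With 1 library of each group left out it came no nearer to 0 than -0.097, against -0.11 with no cluster removed. The 10 most abundant clusters of each library took a mean of 19.0% of the FPKM sum in UH and 17.6% in Ck. Leaving them out could therefore move the median little. Scaling by larger sets of abundant clusters was not tested, such as the 428 described below that took 0.846 to 19.3% of a library. The scaling of FPKM cannot be told apart from a real excess of falls: with median ratio scaling 43.6% of the calls fell, which passed beyond the band of 5 points around 50% set for this test, and that scaling itself moves the median towards 0. That rescaling had first been set as the test of the very abundant clusters and was assigned to scaling only after its result was seen; a change of total RNA in the spiders with group was not tested.

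UH against UL gave the most calls, while the Ck libraries spread widely. The hypothesis that the UH to UL difference runs along the main direction of variation among the Ck libraries (57.3% of their variance, with Ck replicates 1 and 2 at its ends) was tested by the correlation across clusters. Its absolute value was 0.514 and was the highest of 35 splits, but the highest other split reached 0.513 and the median of the others was 0.20. The set criterion was met only by this narrow margin over a split that mixed the groups, so the correlation does not single out the real groups. It does not decide whether a state that varies among the Ck samples takes part in the UH to UL difference. Sex, feeding and moulting state are not given in the labels used here and were not tested, and urea itself stays open.

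UL replicate 3 had 1656 clusters listed above 0 in it alone, against 87 to 315 in the other libraries. They held 2.08% of its FPKM sum. None could be among the tested clusters, because the filter needs at least 1 FPKM in at least 4 libraries. Greater depth is argued against, since 4 libraries were deeper. Rare transcripts caught by chance are argued against for the 540 of these clusters with 10 or more estimated fragments, since the next library had 12 such clusters; over all 1656 that share was 32.6%, between the bounds set. They are argued against for the excess among the others too: UL replicate 3 had 1116 with under 10 fragments and the highest other library 303, though some of the 1116 may still be such transcripts. RNA of another organism in the material of that library, such as prey, is a possible explanation that was not tested, because the sequences were not used here.

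Single libraries stood far from the other 3 of their group in 16 of the 58 groups of values tested. Chance gives about 1 in 20 for normal, independent values, which FPKM values are not, and in 4 of the 16 the other 3 libraries were listed at 0, which by itself meets the limit; no excess over chance is read from the 16. Depth was lowest at 16.57 M fragments in UM replicate 3 and at 18.37 M fragments in UH replicate 1. The most abundant cluster reached 137624 FPKM in UL replicate 1 (44217 to 55259 in the others) and 11.8% of the FPKM sum in UH replicate 1 (8.28 to 8.80% in the others). UM replicate 4 had 1159.7 FPKM of Cluster-9253.84883 (8.62 to 29.48 in the other UM libraries), 115.53 FPKM of Cluster-9253.14435 (1.11 to 2.08) and 0.97 FPKM of Cluster-9253.22097 (listed at 0). Ck replicate 2 had 33.32 FPKM of Cluster-9253.50222 (9.54 to 13.37), Ck replicate 1 had 6.75 FPKM of Cluster-9253.17447 (listed at 0), and Ck replicate 4 had 777.06 FPKM of Cluster-9253.52189 (59.44 to 177) and 0.26 FPKM of Cluster-9253.84883 (0 to 0.04). UL replicate 4 had 16.55 FPKM of Cluster-9253.48374 (0.18 to 2.33), and UH replicate 3 had 1.4 FPKM of Cluster-9253.48350 (0 to 0.1). UL replicate 1 had 0.13 FPKM of Cluster-9253.84883 and UL replicate 2 had 0.07 FPKM of Cluster-9253.14435, both listed at 0 in the other UL libraries and both within what 1 or few fragments give. The 0.97 FPKM of Cluster-9253.22097 in UM replicate 4 is within that too, as the cluster has only 317 bases.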

How the results depend on the processing

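Limma voom on estimated fragments, the removal of clusters listed at 0 in a whole group, the minimum of 500 bases and the removal of 4 libraries together were chosen after seeing the data. Counts within 1.5 times of those reported are not repeated, and unless stated the cause of a difference was not tested. With a pseudocount of 0.1 UL against Ck gave 21 calls. With no filter on low values (135991 clusters tested) UL against Ck gave 11, UH against Ck 1815, UM against UL 67, UH against UM 522 and the F test 3473. UH against UM gave 527 with median ratio scaling and 500 with quantile normalization. In fits of only the 2 groups, with fewer residual degrees of freedom, UL against Ck gave 0 in limma, UM against Ck 5 and UH against Ck 1171. Array weights gave 1099 for UL against Ck, 177 for UM against Ck, 6525 for UH against Ck, 2044 for UM against UL, 4825 for UH against UM and 11992 in the F test. A minimum absolute log2 fold change of 1, which can only remove calls, left 1937 for UH against Ck, 3710 for UH against UL (2387 rose, so the majority turned) and 482 for UH against UM. Voom gave 2 for UL against Ck, 13 for UM against Ck and 460 for UM against UL. Without clusters listed at 0 in a whole group UL against Ck gave 2 and UM against Ck 18. Without the 4 libraries UL against Ck gave 2250, UM against Ck 600 and UH against UM 2569.

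With 1 library left out, counts ranged from 2 to 2135 for UL against Ck, 16 to 341 for UM against Ck, 1709 to 4571 for UH against Ck, 16 to 839 for UM against UL, 7585 to 11498 for UH against UL, 377 to 738 for UH against UM and 3604 to 7950 for the F test. UH against UL was the comparison whose count stayed within 1.5 times for each of its 8 libraries. With the replicate number as a block, UM against Ck gave 12 calls and the other counts stayed within 1.5 times; 5 of 24 pairs of same-numbered libraries had a correlation of deviations over 0.1 (-0.28 to 0.26) and 4 of 16 libraries correlated best with their own number, so the numbers were not taken as pairing. For the clusters named by the rule, each in its comparison with Ck, 88 of 112 values under other settings stayed past the threshold, 24 no longer passed and 0 reversed; of 88 with 1 library left out the figures were 68, 20 and 0. For the other calls on these clusters and on Cluster-9253.48377, whose reruns were chosen after seeing the data, they were 232, 14 and 0 of 246, and 166, 26 and 0 of 192. The camera and fry tests and their alternatives were not run, for want of descriptions. Depth limits values near 1 fragment, so a cluster listed at 0 is not shown to be absent.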

Other observations

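The seeds of the sets of clusters, the 20-fold limit, the minimum of 1 FPKM and the sets of 4 libraries below were all chosen after the values were seen.

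A large set of clusters moved together across the libraries. Cluster-9253.48377 (780 bases) had 8803, 321, 2218 and 2081 FPKM in Ck, 421 to 701 FPKM in UL, 3543 to 6939 FPKM in UM and 8039 to 11332 FPKM in UH. Picked by their likeness to it across the 16 libraries, 1032 clusters, itself included, had r over 0.9 and 428 had r over 0.95. The FPKM sum of the 428 took 0.846% of a library at the lowest and 19.3% at the highest. Cluster-9253.48377 itself was higher in UH than in UL by a log2 fold change of 4.09 ± 0.68 (SE, adjusted p = 0.00109) and in UM than in UL by 3.22 ± 0.68 (adjusted p = 0.0289). Against Ck, UH gave 2.30 ± 0.68 (adjusted p = 0.043), and UL and UM did not pass (adjusted p = 0.227 and 0.442). With 1 library left out the UM to UL call was lost except without UM replicate 4 (highest adjusted p 0.106), and the UH to Ck call except without Ck replicate 1 (highest 0.101; log2 fold change 1.45 without Ck replicate 2). In other settings these calls were lost in 1 of 11 and 3 of 11 (highest adjusted p 0.0763 and 0.154). UL against Ck passed without Ck replicate 2 (adjusted p = 0.00244). Ck replicate 1 lay at the level of UH and Ck replicate 2 below all UL libraries.

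Another set was very abundant in most libraries and nearly missing in some, without following the groups. Cluster-9253.45104 (1482 bases) had 38.8 FPKM in Ck replicate 1, 67.6 in UM replicate 3 and 15.1 in UH replicate 4, against 27194 FPKM in UH replicate 2 and 13024 to 24071 FPKM in UL. Itself included, 27 clusters had r over 0.95, and its ratio to Cluster-9253.45355 stayed between 1.87 and 2.64 in all 16 libraries. The 27 clusters took 0.00698% to 7.67% of a library's FPKM sum. Cluster-9253.45104 did not pass in any of the 6 comparisons (lowest adjusted p 0.3).

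There were 13 clusters at least 20-fold lower in every UH library than in each other library, counting clusters with at least 1 FPKM in all of the others. Their summed FPKM was 1.45 to 3.38 in UH and 668 to 5007 in the other 12 libraries, and their median length was 2036 bases. The same count was 0 for Ck, 0 for UL and 2 for UM. Of all 1820 sets of 4 libraries, 31 had any such cluster.

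Among clusters listed above 0 in exactly 4 libraries, with at least 1 FPKM in each of them, the most belonged to a set across groups. Ck replicates 2, 3 and 4 with UL replicate 3 alone shared 42 clusters, whereas the counts for Ck, UL, UM and UH were 2, 2, 4 and 2. No explanation of these 42 clusters was tested.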
